A study of Mus musculus with 9 samples.

How the data were processed

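Bulk RNA sequencing was analysed for 9 libraries of mouse splenic CD4+ T cells on the C57BL/6 background, 3 in each of 3 groups. Per the labels' protocols, naive CD4+ T cells were sorted by flow cytometry and cultured on plates carrying 1 µg/ml of an antibody against CD3e, which triggers the T cell receptor complex, together with 19 µg/ml of either an antibody against CD40L or an isotype control antibody. Wild-type cells were kept on either antibody, and cells of mice with CD40L deleted in T cells were kept on the isotype antibody. RNA was isolated with a silica-column kit that included a DNase step, and libraries were made with the KAPA mRNA HyperPrep kit, per the labels' protocols. The duration of the culture is not given in the sources used here. Groups and replicate numbers were taken from the sample titles and treatment labels.

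The authors deposited 1 table of expected counts per RefSeq transcript, not normalized, for 42361 transcripts. All values were multiples of 0.5, which was tested on the table, so the values were read as fractional counts rather than whole reads. CASAVA 1.8.2 and HISAT2 2.1.0 and the mouse build mm10 are named in the submitters' processing notes. The counting tool, the use of strand and the handling of reads with several alignments are not given in the sources used here, so values of paralogs, pseudogenes, overlapping genes and antisense pairs are uncertain.

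Gene symbols came from the RefSeq table of assembly GRCm38.p6 for 42198 transcripts and from the GENCODE vM21 annotation for 70, and 93 transcripts had no symbol and kept their identifier. Coordinates are those of GRCm38, the assembly that mm10 represents. Transcripts of 1 gene held nearly the same reads: among genes with several transcripts and many counts, the median ratio of the second to the first transcript total was 0.991. Therefore 1 transcript was kept per gene, the one with the highest total over all libraries, and its counts were rounded to whole numbers with fractions rounded up, which left 25160 genes. Total counts over these genes ranged from 5316482 to 15565711 per library.

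The design assumed whole counts, and the rounded fractional counts took their place in the same test. Genes were kept by the expression filter of edgeR (filterByExpr, by group), which left 11256, and libraries were scaled by the TMM method. The main test was the quasi-likelihood F test of edgeR 4.0.16 with robust estimation in R 4.3.3, fitted to all 9 libraries with 1 term per group, and p-values were adjusted by the Benjamini-Hochberg method within each comparison at a threshold of 0.05. The common biological coefficient of variation was 0.127. Levels are given as CPM, the usual library-size-scaled count, over TMM-scaled library sizes, as mean ± SD over n = 3 libraries, and fold changes as log2 values with their standard error (SE). Nothing in the labels says that the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

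The design gives 3 comparisons: anti-CD40L against isotype antibody in wild-type cells, libraries labelled KO against wild type on isotype antibody, and anti-CD40L wild type against isotype libraries labelled KO. The last also tests the difference between the first 2. For 36 gene lists written before the data were examined, covering T helper subsets, activation, metabolism, signalling and markers of other cell types, the camera test of limma 3.58.1 was run with a preset correlation between genes of 0.01 on the 31 lists with at least 3 tested members, adjusted by Benjamini-Hochberg over the lists. Calls were also counted after adjusting over each list alone. The genes named were chosen by a rule set at the same time: 15 genes of the study's subject whatever their result, the 8 largest changes per direction (4 in the last comparison) among called genes whose groups did not overlap and whose mean reached 1 CPM, the 5 of smallest p where no gene was called, and up to 2 members per direction of each list. Predicted genes, pseudogenes, unnamed identifiers and antigen receptor segments were left out of the choice by size. Some genes that the rule names are not reported here. Exceptions are identified where they occur.

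The first 2 comparisons share the wild-type isotype libraries, so the correlation of their fold changes was set against 100 simulations of unchanged groups. Each test was first tested on simulated data made from the real means and library sizes with 200 genes changed. In the comparison of anti-CD40L with isotype, run on 11256 genes, the test recovered 50.7% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 93.9% of those changed 4-fold. For the libraries labelled KO against wild type, also on 11256 genes, the shares were 53.7%, 74.6% and 89.4%. For anti-CD40L against the libraries labelled KO, on 11256 genes, they were 47.8%, 80.6% and 83.3%. Unchanged genes made up 12 of 159 calls (7.5%), 8 of 156 (5.1%) and 5 of 148 (3.4%) in these simulated comparisons. The first 2 shares lay above the 5% that the threshold aims at. Each comparison was simulated in a single draw, which cannot show whether the test exceeds that share on average.

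Alternatives set before the data were examined were other scalings, DESeq2 1.42.0, limma-voom, no filter and a stricter filter on low counts, a fit of only the groups compared, a replicate term, other list tests and leaving out each library in turn. Alternatives added after seeing the data were the sum of a gene's transcripts, fractions rounded down, limma-voom with library quality weights, and thinning every library to the smallest total. Intervals of count ratios are exact binomial 95% intervals of summed counts; PCR copies are not independent molecules, so these cover counting error only.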

Results

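CD40L, the ligand of CD40 on activated CD4+ T cells, was studied in naive CD4+ T cells stimulated through CD3e, either by binding it with a plate-coated antibody or by using cells of mice with CD40L deleted in T cells. The series title links CD40L to T cell polarization and to RACK1, a scaffold protein of activated protein kinase C. Each of the 3 groups had 3 libraries. Total counts over genes were 11007159, 10757200 and 8796453 for wild-type isotype replicates 1 to 3 and 11226188, 9787896 and 5316482 for wild-type anti-CD40L replicates 1 to 3. They were 9298654, 13411354 and 15565711 for isotype replicates 1 to 3 labelled KO. Anti-CD40L replicate 3 had a count for 11673 genes, while the other libraries had one for 14290 to 17428. It also stood apart on the first principal component, at 86.96 against -19.1 to 10.22 for the others, a component that held 54% of the variance. A transcript without a symbol in the annotations used, NR_046233, took 2.06% ± 0.772 (SD, n = 3) of the counts in wild-type isotype. It took 0.999% ± 0.356 in anti-CD40L and 1.17% ± 0.039 in libraries labelled KO. The wild-type isotype replicates 1 to 3 were at 1.184%, 2.635% and 2.368%, so replicate 1 lay near the libraries labelled KO.

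**Figure D1:**
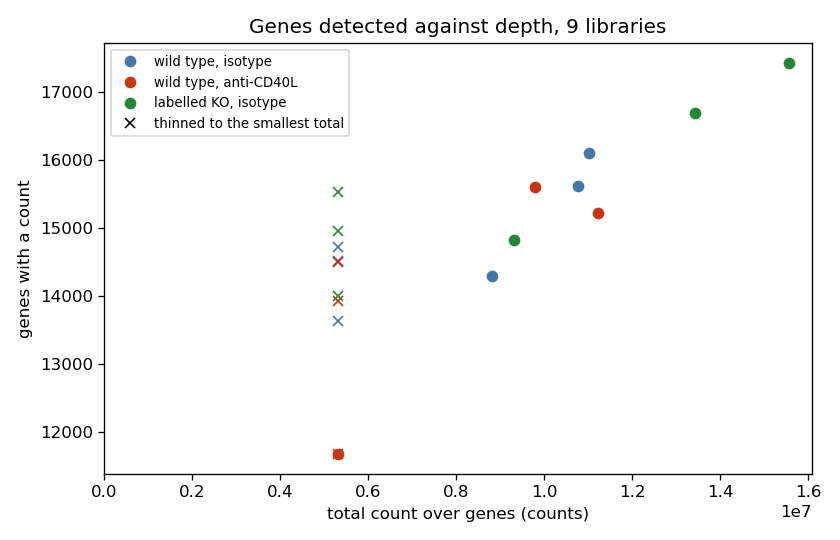
Number of genes with a count (vertical axis, not from 0) against the total count over genes (horizontal axis) for the 9 libraries, colored by group; crosses give the same libraries thinned to the smallest total. Anti-CD40L replicate 3, with 11673 genes, lies below every other library also after thinning.

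The targeted gene was examined first. Cd40lg (NM_011616, chromosome X, 57212143 to 57224042, GRCm38) was at 141.75, 153.63 and 188.92 CPM in wild-type isotype libraries and at 109.34, 132.15 and 162.8 CPM in wild-type anti-CD40L libraries. In the libraries labelled KO it was at 145.12, 136.07 and 150.15 CPM. Means ± SD were 161 ± 24.5, 135 ± 26.8 and 144 ± 7.13 CPM (n = 3 each). Cd40lg in the libraries labelled KO differed from wild type by less than the spread of replicates (log2 fold change -0.17, SE 0.13; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.935). On anti-CD40L the log2 fold change was -0.27 (SE 0.14; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.228), and limma-voom with quality weights called it at 0.0473, within a range of 0.0473 to 0.608 over the alternatives. The values count reads over the whole transcript, and the deleted part of the gene is not given in the sources used here, so this level does not show whether the deletion was present. Directions drawn from these libraries below therefore rest on the label KO alone. Rack1 was at 2023 ± 82.7 CPM in wild-type isotype, 1798 ± 86.8 CPM on anti-CD40L and 1785 ± 243 CPM in libraries labelled KO. It was not called against wild-type isotype (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.28 on anti-CD40L and 0.881 in the libraries labelled KO).

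**Figure D2:**
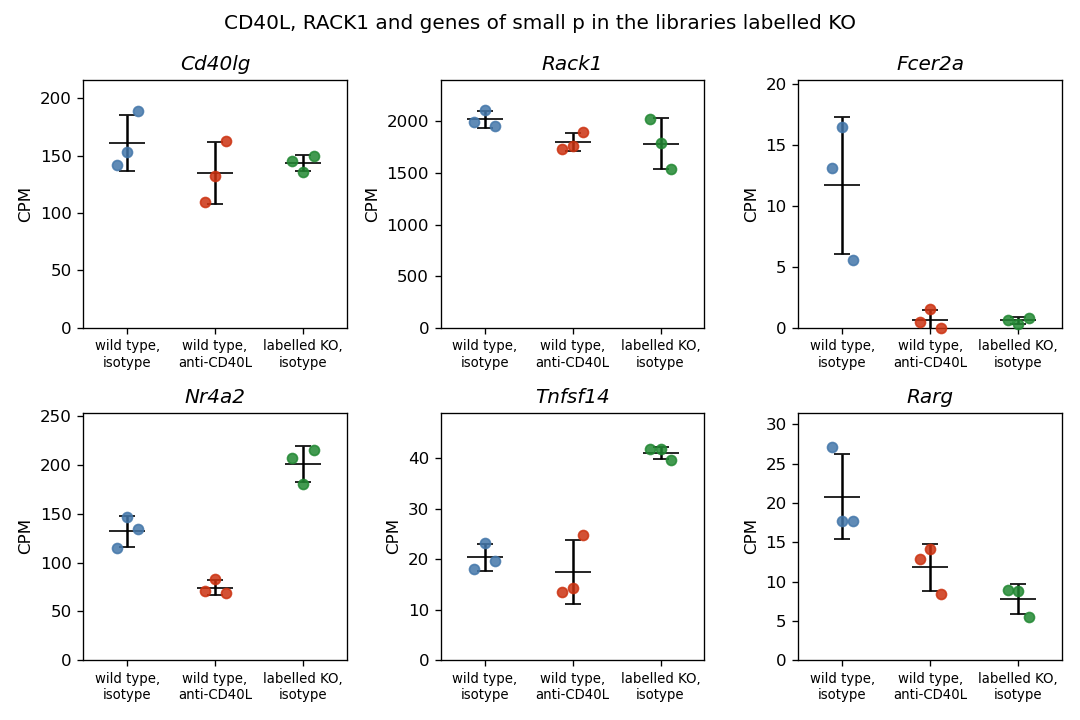
CPM (vertical axes, from 0) of 6 genes in each library, by group; points are libraries, horizontal marks the mean and bars the SD (n = 3, cut off at 0). Cd40lg lies at 136.07 to 150.15 CPM in the libraries labelled KO and at 141.75 to 188.92 CPM in wild-type isotype, and Fcer2a lies at or below 0.827 CPM in the libraries labelled KO.

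The first comparison asked how binding CD40L with an antibody alters the response of wild-type cells. Il7r, the receptor chain for the survival cytokine IL-7, went from 196 ± 49.9 to 10.4 ± 3.09 CPM (n = 3 each), 19.3-fold lower (log2 fold change -4.27, SE 0.23; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.21e-07). S1pr1, which guides exit from lymphoid organs, fell from 239 ± 37 to 38.8 ± 5.36 CPM (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 6.87e-07). Il2, the T cell growth factor gene, rose from 4.99 ± 1.17 to 19.5 ± 11.1 CPM, and Lag3, an inhibitory receptor, from 22.5 ± 5 to 63.2 ± 15.3 CPM (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00398 and 0.000395).

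Of the 20 naive and quiescent T cell genes tested, 11 fell and none rose, and 13 fell when adjusted over the list alone. The list moved down relative to other genes (camera, Benjamini-Hochberg adjusted p = 1.38e-15, and adjusted p = 0.146 with an estimated correlation). Of 29 interferon response genes, 8 fell and none rose, with 12 lower when adjusted over the list alone. That list also moved down (camera, Benjamini-Hochberg adjusted p = 2.51e-06, adjusted p = 0.391 with an estimated correlation, and 0.0563 by fry). Ddx58, the RNA sensor RIG-I, fell by 2.74 on the log2 scale (SE 0.34). Zbp1, a sensor of Z-form nucleic acids, fell by 2.67 (SE 0.47), a call that limma-voom did not make (Benjamini-Hochberg adjusted p = 0.0518, with a range over the alternatives of 1.19e-23 to 0.0545).

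Of 14 genes for CD40L, its receptors and adaptors, 5 fell and 1 rose, or 6 and 2 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00317, and adjusted p = 0.146 with an estimated correlation). Itga4, the integrin chain alpha 4, fell by 1.61 (SE 0.16) and Traf5, a signalling adaptor of TNF receptors, fell by 1.16 (SE 0.16) on the log2 scale. Of 9 follicular helper genes 2 fell, with 4 lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0288, and adjusted p = 0.356 with an estimated correlation). Among them Sh2d1a, the adaptor SAP, fell by 1.16 (SE 0.22). Of 5 Th17 genes 1 fell, the IL-6 receptor chain Il6ra (fell by 0.85, SE 0.12), with 3 lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0294, and adjusted p = 0.356 with an estimated correlation). The follicular helper list was not called without isotype replicate 2 or anti-CD40L replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.0874 and 0.0983). The Th17 list was not called without isotype replicate 3 or anti-CD40L replicate 1 (camera, Benjamini-Hochberg adjusted p = 0.0506 and 0.0571).

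The MYC, glycolysis, cell cycle and cholesterol lists moved up. Of 27 MYC and ribosome biogenesis genes, 6 rose and none fell, and 15 rose when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 2.01e-08, and adjusted p = 0.356 with an estimated correlation). Hspd1, a mitochondrial chaperonin, rose from 1153 ± 75 to 1729 ± 230 CPM and Dkc1, which modifies ribosomal RNA, from 315 ± 11.1 to 422 ± 32.5 CPM. Of 26 glycolysis and hypoxia genes, 4 rose and 1 fell, or 10 and 2 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00453, adjusted p = 0.356 with an estimated correlation, and 0.0544 by fry). Hif1a, the hypoxia-inducible transcription factor, rose by 0.41 on the log2 scale (SE 0.09), and Pdk1, a kinase that restrains pyruvate oxidation, fell by 0.60 (SE 0.13). Of 29 cell cycle genes 1 rose, the ribonucleotide reductase gene Rrm1, also 1 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00876, and adjusted p = 0.356 with an estimated correlation). Of 23 cholesterol synthesis genes 1 rose, the isoprenoid enzyme gene Idi1, also 1 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00847, adjusted p = 0.391 with an estimated correlation, and 0.0785 by fry). Single libraries decided calls here: the highest adjusted p was 0.0647 for Hif1a and 0.0656 for Pdk1 without isotype replicate 1, and 0.0959 for Rrm1 and 0.099 for Idi1 without anti-CD40L replicate 1 (edgeR quasi-likelihood test, Benjamini-Hochberg).

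Activation genes moved both ways. Of 21 tested, 5 rose and 3 fell, or 7 and 6 when adjusted over the list alone, and the list as a whole was not called (camera, Benjamini-Hochberg adjusted p = 0.349). Irf4, a transcription factor induced by T cell receptor signals, rose from 1498 ± 168 to 2353 ± 48.5 CPM, and Tnfrsf4, the costimulatory receptor OX40, from 113 ± 5.69 to 154 ± 12.6 CPM. Nr4a2, an orphan nuclear receptor induced early by the same signals, fell from 132 ± 15.7 to 74.4 ± 8.07 CPM. Il2ra, the IL-2 receptor alpha chain, rose by 0.41 on the log2 scale (SE 0.08). Cd69 and Cd44, activation markers, had log2 fold changes of 0.31 and 0.59 and were not called (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0671 and 0.0744). DESeq2 called both, with Benjamini-Hochberg adjusted p = 0.0236 and 0.0339, within ranges over the alternatives of 0.0189 to 0.2 and 1.44e-05 to 0.298. Single libraries decided these too: without isotype replicate 2 or replicate 3 labelled KO, Cd69 was called (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0433 and 0.0409), and so was Cd44 without anti-CD40L replicate 2, at 0.0474.

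Bcl2l1, which encodes the survival protein BCL-XL, rose by 0.94 (SE 0.13) and Cd200, a receptor ligand that restrains myeloid cells, by 0.75 (SE 0.13) on the log2 scale. Xcl1, a chemokine, fell by 1.19 (SE 0.17), Cxcr4, a chemokine receptor, fell by 1.15 (SE 0.24), and Il18r1, an IL-18 receptor chain, fell by 2.72 (SE 0.40). Of 11 RACK1 and protein kinase C genes 1 rose and 3 fell, or 2 and 4 when adjusted over the list alone, and the list was not called (camera, Benjamini-Hochberg adjusted p = 0.347). Prkca, a conventional protein kinase C, rose by 0.43 (SE 0.09), and Prkd2, a kinase downstream of protein kinase C, fell by 0.91 (SE 0.15). The Prkca call was lost without anti-CD40L replicate 1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0519).

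Gata3 and Foxp3, regulators of Th2 and of regulatory T cells, gave no called change. Gata3 had a log2 fold change of -0.55 (SE 0.26) and Foxp3 of -0.03 (SE 0.15; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.198 and 0.932). Tbx21, Ifng, Il4, Il17a and Cd40 had too few counts for the test. Tbx21, the Th1 regulator T-bet, had 10 counts on anti-CD40L and 17 in isotype libraries, a ratio of 0.681 (interval 0.279 to 1.58). Ifng, the Th1 cytokine, had 18 against 9, a ratio of 2.32 (0.988 to 5.85). Anti-CD40L replicates 1 to 3 held 2, 6 and 10 of these counts, so most came from replicate 3, the library with the smallest total. Il4 had 0 against 2 counts and Il17a none in either group, which is below what this depth can compare.

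Besides Il7r, Il2 and Lag3, the largest changes include Art4, an ADP-ribosyltransferase gene, which fell from 5.14 ± 0.13 to 0.199 ± 0.271 CPM, and Man1c1, a mannosidase gene, which fell from 3.35 ± 1.4 to 0.161 ± 0.153 CPM. Tlr12, a Toll-like receptor gene, fell to 1 count against 58, a ratio of 0.02 (interval 0.000497 to 0.116). Pyroxd2 had 1 against 32, a ratio of 0.0362 (0.000889 to 0.217), and Rnf32 had 3 against 62, a ratio of 0.056 (0.0113 to 0.172). Ly6d had 3 against 68, a ratio of 0.0511 (0.0103 to 0.156). Oasl2, an interferon-induced gene, fell from 3.42 ± 2.16 to 0.153 ± 0.185 CPM. Plod2, a lysyl hydroxylase gene, rose from 0.847 ± 0.182 to 3.79 ± 1.55 CPM, Syt6 from 0.519 ± 0.176 to 2.32 ± 0.826 CPM and Tnip3 from 0.716 ± 0.256 to 2.95 ± 0.616 CPM. Plscr1 rose from 3.46 ± 2.05 to 11.2 ± 3.23 CPM, Poglut3 from 2.22 ± 0.539 to 5.94 ± 1.08 CPM and Lif, a cytokine of the IL-6 family, from 4.71 ± 1.69 to 11.7 ± 2.76 CPM. Calls of these last 6 and of Ly6d and Oasl2 were lost without single libraries. The highest adjusted p was 0.106 for Plod2 without isotype replicate 3, and 0.165 for Tnip3, 0.152 for Ly6d and 0.0642 for Plscr1 without isotype replicate 2 (edgeR quasi-likelihood test, Benjamini-Hochberg). It was 0.126 for Syt6, 0.0915 for Poglut3 and 0.109 for Lif without anti-CD40L replicate 1, and 0.13 for Oasl2 without anti-CD40L replicate 3 (edgeR quasi-likelihood test, Benjamini-Hochberg).

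Among markers of other cell types, Fcer2a, the low-affinity IgE receptor of B cells, fell from 11.7 ± 5.6 to 0.656 ± 0.782 CPM (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00176). Of 9 B cell genes 2 fell, also 2 when adjusted over the list alone, but not both calls held in every alternative. Of 5 monocyte, macrophage and neutrophil genes 3 fell, also 3 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0114, and adjusted p = 0.356 with an estimated correlation). Among them Ctss, a lysosomal protease gene, fell from 79.5 ± 6.52 to 44.9 ± 1.29 CPM. Only 5 of the 17 genes listed were tested. Lyz2 had 0, 5 and 7 counts and Csf1r 0, 1 and 0 in wild-type isotype replicates 1 to 3. Such counts are too few to show whether carried-over myeloid cells fell. Cd40 had 2 counts on anti-CD40L and 34 in isotype libraries, a ratio of 0.0681 (interval 0.00793 to 0.266). It was called by edgeR without the filter (Benjamini-Hochberg adjusted p = 0.0393). That fit also called a gene counted in only 1 library, so this call is uncertain.

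The other lists were not called in this comparison, by camera with Benjamini-Hochberg adjustment over the lists. Adjusted p was 0.144 for Th1, 0.758 for Th2, 0.951 for regulatory T cell, 0.107 for inhibitory receptor, 0.467 for T cell cytokine, 0.107 for chemokine, 0.144 for T cell receptor signalling, 0.179 for NF-kB target and 0.155 for IL-2 and STAT5 target genes (camera, Benjamini-Hochberg). It was 0.159 for ribosomal protein, 0.0756 for oxidative phosphorylation, 0.791 for ATF4, 0.85 for unfolded protein response, 0.127 for apoptosis, 0.124 for cytotoxic and 0.144 for immediate early genes (camera, Benjamini-Hochberg). For B cell, dendritic cell and stromal markers it was 0.205, 0.791 and 0.179 (camera, Benjamini-Hochberg). CD8 T cell, erythroid, sex-linked, natural killer and mitochondrially encoded lists had fewer than 3 tested genes. The median, the mean and the test differed in sign for the regulatory T cell, cytokine, STAT5 and ATF4 lists.

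In all, 1055 of 11256 genes changed, 328 higher and 727 lower, and 282 of them at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg). The groups did not overlap in 32.6% of tested genes, where chance gives 10% on average over splits. The count was 495, 545 and 530 without isotype replicates 1, 2 and 3, and 486 without anti-CD40L replicate 1. Without anti-CD40L replicate 3 it was 989, of which 782 were shared. DESeq2 called 1625, and a fit without the filter called 1698.

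**Figure D3:**
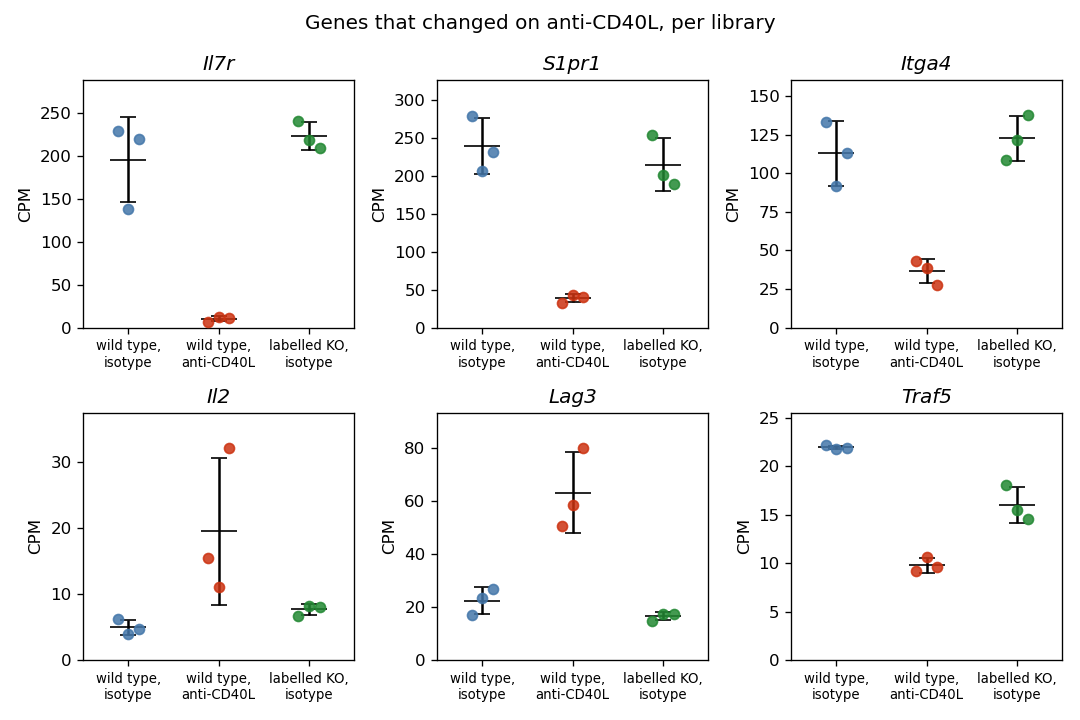
CPM (vertical axes, from 0) of 6 genes in each library, by group; points are libraries, horizontal marks the mean and bars the SD (n = 3). Il7r, S1pr1, Itga4 and Traf5 are lower, and Il2 and Lag3 higher, in all 3 anti-CD40L libraries than in the other groups, with Il7r at 10.4 against 196 CPM in wild-type isotype.

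The second comparison asked what CD40L loss in T cells does without the CD40L antibody, as far as the label KO holds. Fcer2a stood at 0.59 ± 0.272 CPM in the libraries labelled KO against 11.7 ± 5.6 CPM in wild type (n = 3 each). Rarg, a retinoic acid receptor, stood at 7.74 ± 1.91 against 20.8 ± 5.42 CPM, and Lpxn, a focal adhesion protein gene, at 26.1 ± 4.04 against 42.5 ± 1.75 CPM. Nr4a2 stood at 201 ± 18.3 against 132 ± 15.7 CPM, Ndrg1 at 83.3 ± 2.02 against 60.9 ± 1.06 CPM and Tnfsf14, the cytokine LIGHT, at 41.03 ± 1.2 against 20.3 ± 2.6 CPM. None passed the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.109 for Fcer2a and 0.195 for the other 5). DESeq2 and edgeR without the filter called these 6 genes, and limma-voom with quality weights called them except Fcer2a, with Benjamini-Hochberg adjusted p of at most 0.0012, 0.0395 and 0.0166.

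With 0 genes called by edgeR, 649 had an unadjusted p under 0.05, 5.8% of those tested. DESeq2 called 39, limma-voom 0, limma-voom with quality weights 38 and edgeR without the filter 102. A fit of only these 2 groups called 3, Fcer2a, Adam19 and Tnfsf14, of which Adam19 was chosen after its values were seen. The groups did not overlap in 15.2% of tested genes, where chance gives 10% on average over splits. The share of other splits was not computed. A split across the labels gave 673 genes at an unadjusted p under 0.05 by edgeR, above the 649 here, so 15.2% is no evidence of an effect by itself.

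Of 21 activation genes none was called by edgeR, 4 were by DESeq2, and 5 were higher when adjusted over the list alone. The list moved up at a median log2 fold change of 0.15 (camera, Benjamini-Hochberg adjusted p = 2.91e-07, and adjusted p = 0.585 with an estimated correlation). Its members Irf8, a transcription factor, and Nr4a2 had log2 fold changes of 0.61 (SE 0.12) and 0.61 (SE 0.11). The MYC and ribosome biogenesis list moved up at a median of 0.14, with 2 of 27 members below 0, 0 called by edgeR or DESeq2 and 0 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 9.07e-08, and adjusted p = 0.585 with an estimated correlation). T cell cytokines also moved up, with 0 called by edgeR, Tnfsf11 and Tnfsf14 called by DESeq2, and 2 of 11 higher when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00802, and adjusted p = 0.679 with an estimated correlation). These include Tnfsf11, the cytokine RANKL, at 53.7 ± 8.61 against 27.9 ± 6.12 CPM.

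The lists that moved down had 0 members called over all genes by edgeR, while DESeq2 called Eno1, Fdps and Fcer2a among them. Ribosomal proteins were below 0 in 37 of 41 members, with 0 lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 5.66e-06, and adjusted p = 0.771 with an estimated correlation). Oxidative phosphorylation was below 0 in 27 of 30, with 0 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000131, and adjusted p = 0.732 with an estimated correlation). Naive and quiescent genes were below 0 in 14 of 20, with 0 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00152, and adjusted p = 0.679 with an estimated correlation). Tcf7, a transcription factor of naive T cells, had a log2 fold change of -0.26 (SE 0.08). Cholesterol synthesis had 1 lower and glycolysis 3 lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00436 and 0.00634, and adjusted p = 0.69 for each with an estimated correlation). Their enzymes Fdps and Tpi1 had log2 fold changes of -0.42 (SE 0.10) and -0.70 (SE 0.18). B cell genes had 2 lower and T cell receptor signalling genes 0 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0282 and 0.0294, and adjusted p = 0.732 and 0.69 with an estimated correlation). The other 21 lists were not called, with adjusted p from 0.0501 for RACK1 and protein kinase C to 0.971 (camera, Benjamini-Hochberg).

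The activation and MYC lists stayed called whichever library was left out, and fry called none of the 10 lists. Without isotype replicate 1 the naive, cytokine, glycolysis and B cell lists were at adjusted p = 0.239, 0.0503, 0.0503 and 0.117, and without isotype replicate 2 the oxidative phosphorylation, T cell receptor and B cell lists at 0.0538, 0.126 and 0.358 (camera, Benjamini-Hochberg). Without isotype replicate 3 the T cell receptor list was at adjusted p = 0.176, and without replicate 1 labelled KO the cytokine and cholesterol lists were at 0.371 and 0.529 (camera, Benjamini-Hochberg). Without replicate 2 labelled KO the T cell receptor and B cell lists were at adjusted p = 0.101 and 0.433 (camera, Benjamini-Hochberg). Without replicate 3 labelled KO the ribosomal, oxidative phosphorylation, T cell receptor and B cell lists were at adjusted p = 0.324, 0.137, 0.167 and 0.0717 (camera, Benjamini-Hochberg).

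Il2, Il2ra, Cd69, Cd44, Gata3 and Foxp3 were not called by edgeR, with log2 fold changes between -0.15 and 0.63. Tbx21 had 29 counts against 17, a ratio of 1.34 (interval 0.714 to 2.61), Ifng 5 against 9, a ratio of 0.438 (0.115 to 1.45), and Cd40 5 against 34, a ratio of 0.116 (0.0354 to 0.298). Il4 had 3 against 2 counts and Il17a none, which this depth cannot compare.

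**Figure D4:**
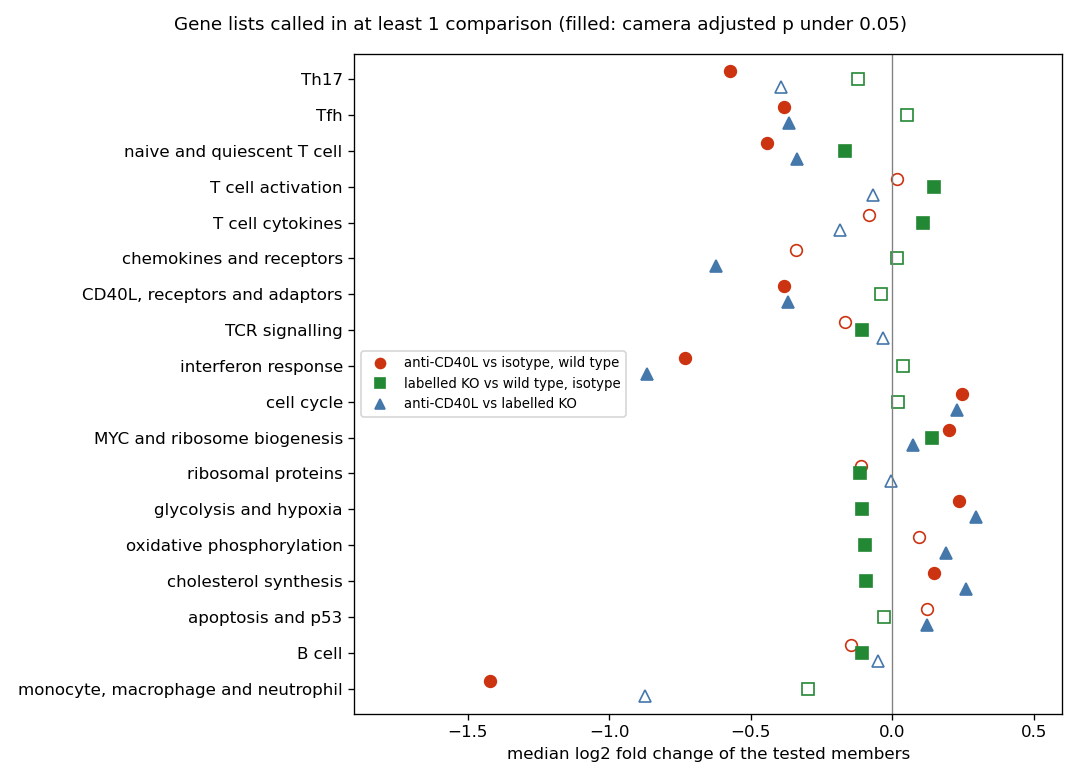
Median log2 fold change of the tested members (horizontal axis) of the 18 gene lists called in at least 1 comparison; circles, squares and triangles are the 3 comparisons, and filled symbols mark an adjusted p under 0.05 by camera with a preset correlation. The interferon list lies at -0.73 on anti-CD40L against isotype and at 0.04 in the libraries labelled KO.

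The last comparison set anti-CD40L wild-type cells against the isotype libraries labelled KO, and tests whether the first 2 effects differ. Il7r was 21.9-fold lower on anti-CD40L, at 10.4 ± 3.09 against 224 ± 16 CPM (n = 3 each; log2 fold change -4.46, SE 0.23; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.49e-07). S1pr1 fell by 2.47 and Itga4 fell by 1.73 on the log2 scale. Xcl1 was lower at 82 ± 22.4 against 287 ± 34.1 CPM. Lag3 was higher at 63.2 ± 15.3 against 16.6 ± 1.61 CPM, as were the glycolytic enzyme genes Tpi1 (184 ± 46.6 against 78.5 ± 1.98 CPM) and Eno1 (531 ± 49.3 against 330 ± 16.6 CPM).

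Of 29 interferon response genes 8 fell, or 17 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.78e-08, and adjusted p = 0.285 with an estimated correlation). Slfn5, an interferon-induced gene, fell by 1.54 on the log2 scale (SE 0.18). Of 20 naive and quiescent genes 7 fell, or 10 with 2 higher when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.47e-10, and adjusted p = 0.187 with an estimated correlation). Of 14 CD40L receptors and adaptors 4 fell, or 8 with 1 higher when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00122, and adjusted p = 0.187 with an estimated correlation). Itgb3, an integrin chain that can bind CD40L, fell by 1.68 (SE 0.24). Of 11 chemokines and receptors 4 fell, or 4 with 1 higher when adjusted over the list alone, and of 9 follicular helper genes 2 fell, also 2 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0188 for each, and adjusted p = 0.278 for each with an estimated correlation).

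Of 26 glycolysis and hypoxia genes 9 rose and 2 fell, or 11 and 2 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.13e-06, and adjusted p = 0.278 with an estimated correlation). Of 23 cholesterol synthesis genes 4 rose, or 8 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 2.12e-06, and adjusted p = 0.278 with an estimated correlation). Fdps, an isoprenoid enzyme gene, rose by 0.53 (SE 0.10). Of 30 oxidative phosphorylation genes 2 rose, or 3 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.78e-05, adjusted p = 0.385 with an estimated correlation, and 0.0692 by fry). Cell cycle and MYC lists had 1 member higher each, also 1 each when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00555 for each, and adjusted p = 0.278 and 0.442 with an estimated correlation). They were Mcm6, a DNA helicase subunit gene, and Hspd1, and the MYC list was at 0.0692 by fry. Of 20 apoptosis genes 3 rose, among them the p53 target Zmat3, or 4 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.047, adjusted p = 0.278 with an estimated correlation, and 0.0508 by fry).

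Single libraries decided some calls. The follicular helper list was at 0.0931 without anti-CD40L replicate 1 and 0.0505 without replicate 3 labelled KO, the chemokine list at 0.0514 without replicate 1 labelled KO, and the apoptosis list at 0.117 without anti-CD40L replicate 2 and 0.0874 without replicate 2 labelled KO (camera, Benjamini-Hochberg adjusted p). The highest adjusted p was 0.0788 for Mcm6 without anti-CD40L replicate 1 and 0.113 for Hspd1 and 0.0617 for Zmat3 without replicate 2 labelled KO (edgeR quasi-likelihood test, Benjamini-Hochberg). The other 20 lists were not called, with adjusted p from 0.0509 to 0.919 (camera, Benjamini-Hochberg). None of 9 B cell genes was called, and 1 of 5 monocyte, macrophage and neutrophil genes fell, or 3 when adjusted over the list alone.

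Among the largest changes, Tlr12 had 1 count against 60, a ratio of 0.0245 (interval 0.000611 to 0.142), and Pyroxd2 1 against 44, a ratio of 0.0334 (0.000828 to 0.196). Oasl2 had 5 counts against 122, a ratio of 0.0603 (0.0192 to 0.145). Il2 rose from 7.69 ± 0.846 to 19.5 ± 11.1 CPM, Ppic, a cyclophilin gene, from 3.69 ± 0.694 to 10.8 ± 3.5 CPM and Tnip3 from 0.707 ± 0.454 to 2.95 ± 0.616 CPM. The highest adjusted p leaving out a library was 0.102 for Il2 without replicate 1 labelled KO, 0.0516 for Ppic and 0.192 for Tnip3 without replicate 2 labelled KO, and 0.146 for Oasl2 without anti-CD40L replicate 3 (edgeR quasi-likelihood test, Benjamini-Hochberg). Oasl2, at 9.21, 1.32 and 1.21 CPM in the libraries labelled KO, went from a log2 fold change of -4.25 to -2.69 without replicate 1 labelled KO and to -5.6 without anti-CD40L replicate 1, and was called in neither fit (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.128 and 0.0631). Il2ra, Cd69, Cd44, Cd40lg, Rack1, Gata3 and Foxp3 were not called by edgeR, with log2 fold changes between -0.71 and 0.63. DESeq2 and limma-voom with quality weights called Il2ra and Cd44, and edgeR without the filter Cd44 and Gata3. Without replicate 3 labelled KO both Il2ra and Cd44 were called, and Cd44 without anti-CD40L replicate 2 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0439, 0.0487 and 0.0462). Ifng had 18 counts against 5, a ratio of 5.29 (interval 1.89 to 18.2), which edgeR without the filter did not call (Benjamini-Hochberg adjusted p = 0.255). Of the 18 counts, 10 came from anti-CD40L replicate 3, so the ratio leans on that library. Tbx21 had 10 against 29, a ratio of 0.507 (0.22 to 1.07), and Cd40 2 against 5, a ratio of 0.588 (0.056 to 3.59). Il4 had 0 against 3 counts and Il17a none.

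In all, 769 of 11256 genes differed, 202 higher and 567 lower on anti-CD40L (edgeR quasi-likelihood test, Benjamini-Hochberg). The groups did not overlap in 26.2% of tested genes, where chance gives 10% on average over splits. The count was 448 without anti-CD40L replicate 1, and 447 and 346 without replicates 1 and 2 labelled KO. It was 481 in a fit of these 2 groups alone, 1219 by DESeq2, 1305 without the filter and 1458 by limma-voom with quality weights.

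Fold changes of the first 2 comparisons, which share the wild-type isotype libraries, correlated across 11256 genes at 0.307 (Spearman 0.374), and genes are not independent replicates. Simulated unchanged groups, with all 9 libraries redrawn from the wild-type isotype means, gave 0.496 (SD 0.0165). Each gene was drawn independently, so deviations that genes of a library share are left out. The simulated SDs may therefore be too small. The covariance was 0.0428 against a simulated 0.0384 (SD 0.0018), a difference of 0.00441, and 64.5% of genes had the same sign against 66.7% simulated. No gene was changed in the simulations, while 1055 were called on anti-CD40L against isotype. Effects in that comparison alone can lower both the correlation and the same-sign share. Their values below the simulated ones therefore do not show that the 2 comparisons agree less than unchanged groups would. No gene was called in both, with 0 expected from independent lists, since edgeR called 0 in the second comparison, where 649 had an unadjusted p under 0.05 and DESeq2 called 39. The 3 shared libraries are too few to be split, so part of any excess may come from them.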

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

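The sum of transcripts, fractions rounded down, quality weights and thinning were tests chosen after seeing the data. Of 2852 values of named genes, called or not, under an alternative, 2582 kept direction and side of the threshold, 206 lost the call, 53 gained it and 11 changed sign. Counted per gene, 34 of 65 named calls on anti-CD40L against isotype held in every alternative, and 30 were lost without a single library. For anti-CD40L against the libraries labelled KO, 15 of 28 held and 13 were lost in this way. Gene counts on anti-CD40L against isotype went from 1055 to 1625 with DESeq2, 1698 without the filter, and 486 to 1342 leaving out a library. The fit without the filter tests more genes, but Fcer2a, tested in both fits, also changed. In the libraries labelled KO it went from 0.109 to 7.27e-21 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p). That fit also called S100a9, chosen after its values were seen, with 43 counts in replicate 1 labelled KO and 0 in every other library. Its calls are therefore uncertain. For the libraries labelled KO the 0 genes became 39 with DESeq2, 102 without the filter, 3 with only the 2 groups, 38 with quality weights and 0 to 2 leaving out a library: Fcer2a without anti-CD40L replicate 2, Fcer2a and Tnfsf14 without replicate 3, and H2-Q6 and H2-Q8 without replicate 1 labelled KO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.04, 0.037, 0.0118, 0.000434 and 0.00691). H2-Q6 and H2-Q8 are paralogs that can share reads and were chosen after their values were seen. For anti-CD40L against the libraries labelled KO, 769 became 1219, 1305, 481, 1458 and 346 to 1022 in the same order. With an estimated correlation 0 lists were called in each comparison, against 10, 10 and 11; fry called 0 for the libraries labelled KO, and leaving out a library gave 6 to 11 there, the 6 without wild-type isotype replicate 1. The correlation of 0.307 moved to 0.399 without the filter, 0.342 with only the 2 groups, 0.263 with summed transcripts and 0.157 (without replicate 3 labelled KO) to 0.38 leaving out a library. Apart from these fits with fewer samples or other gene sets, the cause was not tested.

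Log2 fold changes near 0, not called in any setting where the sign changed, were in leaving out a library -0.096 to 0.056 for Foxp3 on anti-CD40L against isotype, -0.154 to 0.137 for Cd44 in the libraries labelled KO, and -0.243 to 0.04 for Cd40lg, -0.072 to 0.046 for Cd69 and -0.085 to 0.12 for Rack1 on anti-CD40L against the libraries labelled KO. Thinning gave 0.054 for Cd44 and quality weights -0.033 for Rack1; the cause was not tested.

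The replicate numbers were not taken as pairs, since same-numbered libraries correlated in their deviations between -0.149 and 0.18 over the 3 groups. Between wild-type isotype and anti-CD40L these were 0.18, 0.084 and 0.078, against -0.106 to 0.013 for other numbers, and every library correlated best with its own number, a hint of pairing from the data and not the design; this did not hold with the libraries labelled KO. With a replicate block 954, 0 and 664 genes were called, with 617 at an unadjusted p under 0.05 for the 0. Depth limits Tbx21, Ifng, Il4, Il17a and Cd40, which had at most 34 counts in a group.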

Other observations

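Tests chosen only after the result was seen are those of symbol families, the other B cell genes and Fcer2a as a check of the label. So are the naive list score, fry as a check of differences between libraries, and the NR4A and EGR genes. The naive list scores of anti-CD40L replicates 1 and 2, the naive list without anti-CD40L replicate 3, and the other splits were also chosen then. The tests of CD40-induced genes, of thinned detection and of spread were set beforehand.

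Genes were grouped by the letters of their symbols into 286 families with at least 6 tested members, and each was tested for an excess of called genes on anti-CD40L against isotype (one-sided Fisher's exact test, Benjamini-Hochberg over families). This test takes genes as independent, while members of a family may move together or share reads. Its p-values do not measure the spread between libraries. The Gimap family, GTPases of lymphocyte survival, had 6 of 8 members lower and none higher (adjusted p = 0.000509, Fisher's exact test): Gimap4 fell by 1.34 on the log2 scale (SE 0.15), Gimap3 fell by 0.63, Gimap8 fell by 0.60, Gimap9 fell by 0.44, Gimap1 fell by 0.43 and Gimap6 fell by 0.41. Genes named Il, interleukins and their receptors, had 8 of 27 lower and 2 higher (adjusted p = 0.0307, Fisher's exact test). Besides Il7r, Il18r1, Il6ra and Il4ra these were Il10ra, which fell by 1.34 (SE 0.28), Il17ra, which fell by 0.66, Il16, which fell by 0.66, and Il1rl2, which fell by 0.75. These genes were named after their values were seen.

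Fcer2a and Cd40 had lower mean levels than in wild-type isotype libraries both on anti-CD40L and in the libraries labelled KO: Fcer2a had 146, 173 and 48 counts in wild-type isotype, 5, 15 and 0 on anti-CD40L and 6, 4 and 13 in the libraries labelled KO. Fewer carried-over B cells would lower other B cell genes alike. But 9 with at least 10 counts, a set that left out genes which had shown the pattern and was foreseen as 8, had a median log2 fold change of 0.123 in the libraries labelled KO, from -1.04 for Ms4a1 to 1.49 for Blk. On anti-CD40L their median was -0.143 (SE 0.331), from -1.61 for Cr2 to 0.415 for Cd79b, with Ms4a1 and Pax5 at -1.25 and -1.15; since the set left out called genes, fewer B cells stay open there. A hypothesis is that antigen-presenting cells carried over despite the CD4+ T cell sort, with Cd79a at 2.01, 1.69 and 2.86 CPM in the 3 groups, had lost CD40-dependent expression. A summed set of 8 CD40-induced genes was at 9.06 ± 4.2 CPM in wild-type isotype, 3.38 ± 0.741 on anti-CD40L and 5.07 ± 0.749 in the libraries labelled KO (exact one-sided permutation p = 0.0357, 3 against 6 libraries). This stays open, since every wild-type isotype library had to exceed the other 6 and replicate 3, at 4.59 CPM, lay below replicate 1 labelled KO, at 5.74 CPM, and whether the libraries labelled KO came from cells with intact CD40L cannot be told apart either: their highest Fcer2a level was 0.15 times the lowest of wild-type isotype, but Fcer2a was picked for showing the pattern.

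The fall of naive and quiescent genes on anti-CD40L was set against 3 explanations. Differences between libraries of the size seen within groups are argued against by fry. It is an alternative list test that uses that spread and is adjusted over all lists (fry, Benjamini-Hochberg adjusted p = 0.00326). Camera with an estimated correlation, which sets the list against other genes, gave an adjusted p of 0.146. The labels do not say whether the libraries of a group came from separate wells. That spread may therefore hold no differences between wells, and fry cannot decide on those. The gap between the group means of the list was 2.2 times the largest range within a group, but the list was picked for its fall. Larger differences shared by a group's libraries also stay open. The shallow anti-CD40L replicate 3 as the cause is argued against too, since replicates 1 and 2 scored at least 0.57 log2 CPM below every wild-type isotype library over all 20 genes, against a largest range within a group of 0.374. Without replicate 3 the median log2 fold change of the 20 genes was -0.491 (SE 0.311 over genes), against -0.442 with it, too wide to decide alone. A stronger immediate T cell receptor signal at harvest would raise NR4A and EGR genes, and their median log2 fold change was -0.569 (SE 0.106 over genes). These genes were chosen after Nr4a2 had been seen to fall, while Irf4, also induced by such signals, rose. The median therefore cannot decide on this signal. A direct action of the CD40L antibody stays open, as untested.

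Anti-CD40L replicate 3 stood apart and held fewer genes. Depth alone is argued against, since every other library thinned to the same total still had at least 16.8% more genes with a count. Fewer distinct molecules in the library may account for it: the spread of its log2 ratios to anti-CD40L replicate 1 was 1.9 times that of replicate 2 at 5 to 20 CPM and 1.4 times above 200 CPM. No biological explanation was tested.

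With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. On anti-CD40L against isotype the real split gave 1055 genes and the highest other 0, so 1 of 10 was as large. For the libraries labelled KO the real split gave 0 genes by edgeR, with 649 at an unadjusted p under 0.05 and 39 by DESeq2, the highest other 2, and 10 of 10 were as large, which a real count of 0 makes certain. The highest other at an unadjusted p under 0.05 was 673. For anti-CD40L against the libraries labelled KO the real split gave 769, the highest other 0, and 1 of 10 was as large.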
